A study of Homo sapiens with 6 samples.

How the data were processed

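Messenger RNA was measured in 6 libraries of H1092, an established small cell lung cancer line that the labels assign to the neuroendocrine ASCL1 subtype. In 3 libraries the cells had been exposed for 24 h to 2 µM bafilomycin A1 (BafA1), an inhibitor of the vacuolar proton pump (V-ATPase) that blocks acidification of lysosomes and autophagic degradation, and in 3 to the vehicle DMSO (5 µL). Per the labels' protocols, RNA was selected with oligo(dT) beads, strand was marked with dUTP, and read pairs of 150 bases per end were sequenced on a NovaSeq. Per the submitters' processing notes, the tools were cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR and the genome build was hg38. The notes give these tools no roles, and how the counts were made, and whether with strand, is not given in the sources used here.

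The deposited table held 38696 genes with 1 column of estimated counts and 1 column of FPKM per library. The deposited values in the count columns were whole-number expected (estimated) counts, not normalized, and summed to 50463874 to 60104665 per library. Low counts piled up at multiples of 4 (1431 genes had 4 counts in DMSO replicate 1, against 834 with 3 and 528 with 5), so 1 count was probably worth less than 1 read pair, and 4 counts were taken as 1 pair. The number of pairs was then smaller than the number of counts by that factor. The FPKM columns, normalized for gene length and library total by the authors per the file headers, entered no test. Counts divided by FPKM gave 1 common total per library, within 0.007% over 15 mitochondrial genes. Gene coordinates are those of the deposited table. Of its gene IDs, 36604 were in GENCODE release 29 for the same build, 100% of them on the same chromosome and 99.98% overlapping the annotated span. Gene symbols are those of the table, and where a symbol stood for more than 1 gene (57 symbols), the gene with the highest total count was used for lists.

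Genes with enough counts by edgeR's filterByExpr were kept (22050 of 38696), libraries were scaled by TMM, and groups were compared with edgeR's two-sided quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), without a block and with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Expected counts were already whole, so rounding changed nothing. Log2 fold changes are BafA1 over DMSO, their standard errors (SE) come from the fold change and the F statistic, and levels are CPM values (counts scaled to the library total and by TMM). Genes were drawn in figures with matplotlib 3.10.9 under Python 3.11.15.

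The design, the tests, 33 gene lists and the rule for named genes were fixed before the data were examined. The lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and beside it with camera at an estimated correlation and with fry. Named genes were the 12 with the largest positive and the 12 with the largest negative fold change among genes with an official-looking symbol that passed the threshold, had a mean of at least 5 CPM and no overlap between groups. A fixed set of genes was named whatever its values, and up to 2 members per direction with the largest fold change were taken from each list.

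The procedure was tested on simulated data drawn from these libraries' means and sizes, with 200 of 22050 genes changed. The filter left 21381 of them in the fit, and changed genes that it removed counted as not recovered. At folds of 1.5, 2 and 4 the procedure recovered 35.8%, 46.3% and 74.2% of the changed genes, or 48%, 76.9% and 95.8% of those with a mean of at least 1 CPM. Of the calls, 7.96% were false, with a far smaller share of genes changed than the 26.1% that passed in the data. A list of shifted genes was called and 0 of 33 lists of unshifted genes were. Simulated genes varied independently of each other, while estimated correlations within the real lists reached 0.866. The simulation therefore cannot show how often lists of correlated genes are called falsely.

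Where a gene had 0 counts in a whole group, the fold is a lower bound against a floor of 12 counts per library, that is 3 read pairs, or 0.213 CPM. Floors and intervals cover counting error only, because reads without molecular identifiers are not independent molecules. Members of gene families with near-identical copies (metallothioneins, histones, HLA genes, HSPA1A and HSPA1B), overlapping genes and antisense genes are uncertain, since the sharing of reads between them is not documented.

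The alternatives were a replicate block, leaving out each library in turn, no filter or a CPM of at least 5 in 3 libraries, DESeq2 size factors, library size only, the DESeq2 Wald test (DESeq2 1.42.0), genes with official-looking symbols only, and edgeR's glmTreat against a fold of 1.5. Counts divided by 4 and the removal of MVD, NPC2 and CLN5 from lists they do not belong to were added after the data had been seen. Within groups, library pairs correlated at 0.968 to 0.975 (log2 CPM, across genes) and differed by more than sampling noise (chi-square per degree of freedom 3.15 to 20.2 on counts divided by 4), so none were merged as copies of 1 library. This does not show that they came from separate cultures.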

Results

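H1092 cells were compared after 24 h with 2 µM BafA1 or with DMSO, with 3 libraries per group, to learn which transcripts differ when the V-ATPase and autophagic degradation are inhibited. Total estimated counts were 57795314, 50463874 and 59893627 in DMSO replicates 1 to 3 and 60104665, 57955334 and 55644043 in BafA1 replicates 1 to 3. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

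With BafA1, 31 of 31 tested genes of the ATF4 amino acid response and 24 of 25 of cholesterol synthesis and uptake rose, and 28 of 28 of mitosis fell (adjusted p = 0.165 for each list with an estimated correlation). TRIB3, a pseudokinase induced by ATF4, rose from 29.1 ± 9.82 to 238.8 ± 4.94 CPM (SD, n = 3), a fold of 8.22. HMGCR, the rate-limiting enzyme of cholesterol synthesis, rose 2.13-fold, and TFRC, the transferrin receptor, rose 2.75-fold. MKI67, a proliferation marker, fell from 535.8 ± 17.8 to 349.1 ± 14.1 CPM (SD, n = 3). ASCL1, which defines the subtype, stood at 965.5 ± 69.2 and 954.0 ± 11.8 CPM (SD, n = 3) and did not pass the test. Of 22050 genes tested, 3073 were higher and 2677 lower with BafA1 (26.1% in all), and 580 of the higher and 507 of the lower differed at least 2-fold. Without BafA1 replicate 1 the count of changed genes dropped to 3756, and without BafA1 replicate 3 to 3827. Where a CPM of at least 5 in 3 libraries was required, 279 higher and 151 lower genes differed at least 2-fold. With library size only, 2768 genes were higher and 3068 lower. The groups did not overlap in 9440 genes (42.8%), where chance gives 10%.

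**Figure D1:**
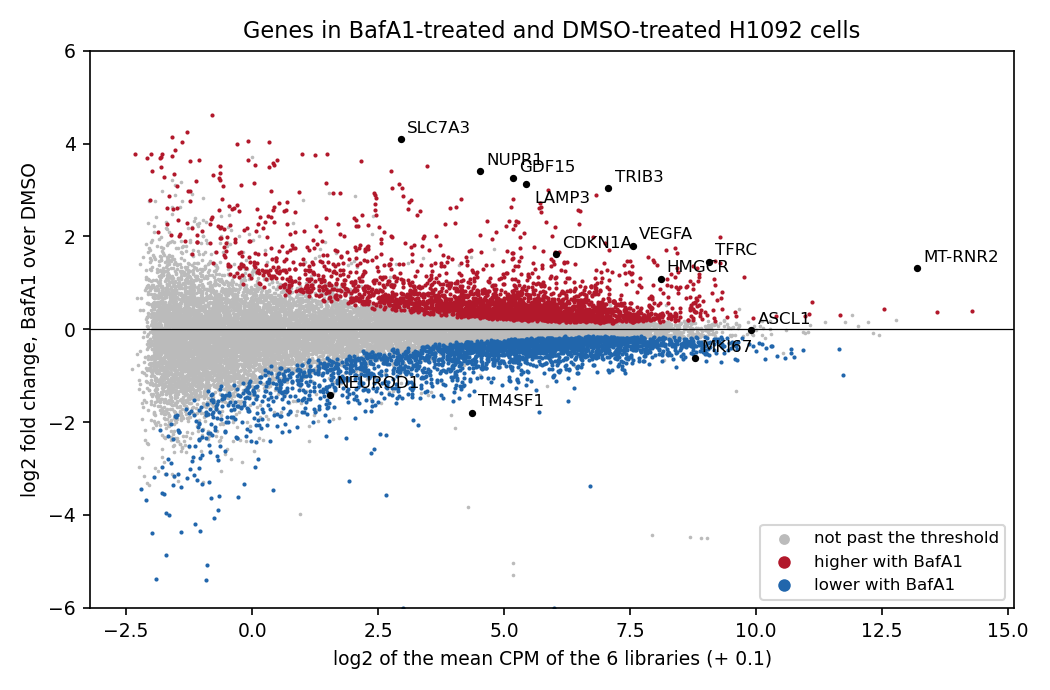
Log2 fold change of BafA1 over DMSO against the log2 mean CPM (plus 0.1) of the 6 libraries, 1 point per tested gene, red for genes higher and blue for genes lower at an adjusted p under 0.05 and grey for the rest. Black points mark 14 named genes, among them TRIB3 at 3.04 and ASCL1 at −0.02, and 23 genes lie outside the axis limits of ±6.

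The 12 largest increases named here were taken among genes with a mean of at least 5 CPM. SLC7A3, a cationic amino acid transporter (ENSG00000165349, chromosome X, 70925579 to 70931125, minus strand, hg38), rose from 0.845 ± 0.261 to 14.4 ± 3.02 CPM (SD, n = 3), a log2 change of 4.099 (SE 0.25; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.46e-05). ASS1, the argininosuccinate synthase, rose by 3.00 on the log2 scale. LAMP3, a lysosome-associated membrane protein (ENSG00000078081, chromosome 3, 183122215 to 183162882, minus strand, hg38), rose from 8.82 ± 2.75 to 77.2 ± 4.20 CPM (SD, n = 3), a log2 change of 3.13. The stress-induced NUPR1 and GDF15, a secreted cytokine of cell stress, rose by 3.41 and 3.25. COL16A1 (3.51), L3MBTL2-AS1 (3.41), MEF2B (3.12), TM6SF1 (3.04), the peptide hormone gene ADM2 (3.04), TRIB3 (3.04) and INO80B-WBP1, an entry that overlaps other genes, completed the 12.

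Among the 12 largest decreases, TM4SF1, a tetraspanin-like membrane protein, fell from 31.8 ± 3.62 to 9.17 ± 1.32 CPM (SD, n = 3), a log2 change of −1.80 (SE 0.13; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.90e-05). BTBD17 fell from 80.2 ± 11.7 to 23.2 ± 1.68 CPM (SD, n = 3). SPTA1, erythroid alpha-spectrin, had a log2 change of −2.25, PKD1L3 of −2.06, SEMA3A, a secreted axon guidance factor, of −1.76 and PTPRT, a receptor phosphatase, of −1.66. ZBTB20 had −1.95, with a DMSO level of 14.3 ± 14.5 CPM (SD, n = 3) that DMSO replicate 2 set, since the change was −0.69 without that library (adjusted p 0.0165), and its call was lost when any single BafA1 library was left out (adjusted p 0.107 to 0.114). The mitochondrial tRNAs MT-TQ (−2.66), MT-TM (−2.58) and MT-TI (−1.64) and the overlapping entries SENP3-EIF4A1 and ARHGAP11A-SCG5 made up the rest.

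Every one of the 31 tested members of the ATF4 amino acid response list rose, with a median log2 change of 1.76, and 31 passed when adjusted over the list alone (camera adjusted p = 3.96e-90; adjusted p = 0.165 with an estimated correlation). DDIT3, which encodes CHOP, rose from 12.5 ± 3.15 to 63.0 ± 5.45 CPM (SD, n = 3). Of 23 unfolded protein response genes, 11 rose, 7 fell and 5 did not pass, and the counts adjusted over the list alone were also 11 and 7 (camera adjusted p = 8.48e-05; adjusted p = 0.347 with an estimated correlation). Leaving out single libraries gave 11 that rose and 4 to 9 that fell, the 9 without DMSO replicate 2. The median log2 change of this list was only 0.02, although camera called it up. The sensor ERN1 (2.08) and HERPUD1 (1.38), a component of degradation at the endoplasmic reticulum, rose, while the chaperones SDF2L1 (−0.48) and CALR (−0.45) fell. Of 20 p53 targets, 8 rose and 2 fell, and 9 rose and 2 fell when adjusted over the list alone (camera adjusted p = 2.43e-05; adjusted p = 0.180 with an estimated correlation). Over the libraries left out, 6 to 8 rose and 1 to 2 fell. BBC3 (2.82), SESN2 (2.58) and the cell cycle inhibitor CDKN1A (1.62) rose and BTG2 (−0.36) and POLH (−0.23) fell. Of the 20 p53 targets, 4 are shared with other lists, among them SESN2 with the ATF4 list and BBC3 with the apoptosis list. Of 21 apoptosis regulators, 7 rose and 2 fell, both over all genes and adjusted over the list alone (camera adjusted p = 0.00378; adjusted p = 0.403 with an estimated correlation). Counts without 1 library were 6 to 7 that rose and 1 to 5 that fell. The 5 were without DMSO replicate 2, where 6 rose. HRK (2.89) rose and BIK (−0.97) and BCL2L1 (−0.31) fell.

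Of 25 genes of cholesterol synthesis and uptake, 24 rose and 1, PMVK (−0.29), fell, with a median of 0.97 and the same counts when adjusted over the list alone (camera adjusted p = 2.03e-40; adjusted p = 0.165 with an estimated correlation). When 1 library was left out, 24 rose and 0 to 1 fell. HMGCS1 rose from 308.1 ± 74.8 to 859.7 ± 36.8 CPM (SD, n = 3) and LDLR, the LDL receptor, from 40.4 ± 6.69 to 110.9 ± 4.56 CPM (SD, n = 3). PCSK9, which lowers the LDL receptor protein, rose by 3.26 at under 1 CPM. Of 15 fatty acid synthesis genes, 11 rose and 0 fell, and 12 rose when adjusted over the list alone (camera adjusted p = 5.26e-09; adjusted p = 0.180 with an estimated correlation, and 10 to 12 rose and 0 fell over the libraries left out); ACSS2 rose by 1.81 and MVD by 1.23. MVD is a sterol enzyme that the list, fixed before the data were examined, holds wrongly, and without it 10 of 14 rose and 0 fell (camera adjusted p 4.49e-07, and 0.206 with an estimated correlation). Of 14 iron handling genes, 8 rose and 0 fell, and 11 rose when adjusted over the list alone (camera adjusted p = 3.29e-06; adjusted p = 0.180 with an estimated correlation). With each library left out in turn, 6 to 8 rose and 0 fell. TFRC rose from 285.6 ± 17.8 to 784.8 ± 27.0 CPM (SD, n = 3), and the ferrireductase STEAP3 rose by 0.97.

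In the autophagy receptor list, 10 of 15 members rose and 1 fell, and 12 rose and 1 fell when adjusted over the list alone (camera adjusted p = 5.82e-07; adjusted p = 0.180 with an estimated correlation). Leaving out single libraries gave 7 to 11 that rose and 0 to 2 that fell. SQSTM1, the receptor p62, rose from 81.4 ± 8.17 to 139.6 ± 6.12 CPM (SD, n = 3), CALCOCO2 by 1.52 and OPTN by 1.09 on the log2 scale, and FUNDC1, a mitophagy receptor, fell (−0.46). Of 34 autophagy core genes, 14 rose and 0 fell, and 16 rose when adjusted over the list alone (camera adjusted p = 4.47e-05; adjusted p = 0.195 with an estimated correlation). Over the libraries left out, 10 to 15 rose and 0 to 1 fell. WIPI1 rose by 1.81, GABARAPL1 by 1.07 and MAP1LC3B, which encodes LC3B, from 75.2 ± 0.421 to 122.4 ± 3.38 CPM (SD, n = 3). Lysosomal hydrolases split into 14 that rose, 3 that fell and 20 that did not pass, or 15 and 4 past when adjusted over the list alone (camera adjusted p = 2.02e-04; adjusted p = 0.347 with an estimated correlation). Counts without 1 library were 12 to 16 that rose and 2 to 4 that fell. NEU1 and GAA each rose by 0.85 and CTSC (−0.64) and ARSB (−0.54) fell. Of 21 lysosomal membrane proteins, 8 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 8.48e-05; adjusted p = 0.180 with an estimated correlation, and 8 to 9 rose and 0 fell over the libraries left out); NPC2 rose by 1.38 and LAMP2 by 0.66. NPC2 and CLN5 are soluble proteins that the list holds wrongly, and without them 7 of 19 rose and 0 fell (camera adjusted p 5.99e-04, and 0.206 with an estimated correlation). For the 18 subunits and accessory proteins of the V-ATPase, BafA1's target, 3 rose, 1 fell and 14 did not pass, or 2 and 1 past when adjusted over the list alone (camera adjusted p = 0.842; adjusted p = 0.942 with an estimated correlation). When 1 library was left out, 2 to 4 rose and 1 to 3 fell. Without DMSO replicate 2, 2 rose and 3 fell. ATP6V1H rose by 0.39 and ATP6V0A1 by 0.26, and ATP6V0E2 fell (−0.45). TFEB, a transcription factor of lysosomal genes, rose by 0.50.

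**Figure D2:**
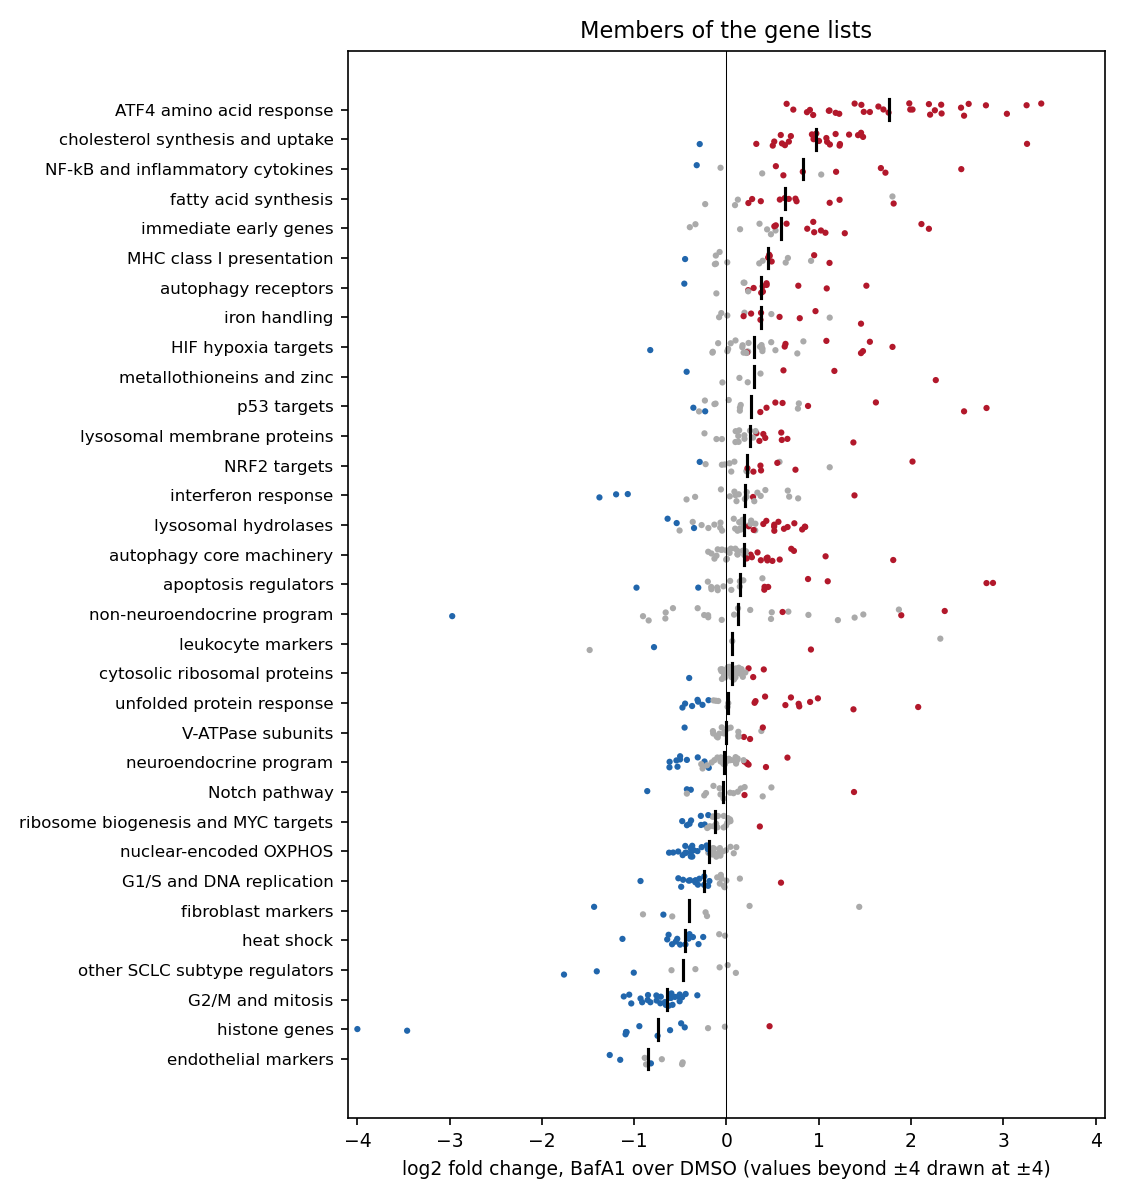
Log2 fold change of BafA1 over DMSO for each tested member of the 33 gene lists, 1 point per gene, red for higher and blue for lower at an adjusted p under 0.05, grey for the rest, with black bars at list medians and values beyond ±4 drawn at ±4. The ATF4 list has the highest median (1.76), and the endothelial list the lowest (−0.84).

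In the HIF target list, 9 of 32 genes rose and 1 fell, and 10 rose and 1 fell when adjusted over the list alone (camera adjusted p = 8.48e-05; adjusted p = 0.509 with an estimated correlation). With each library left out in turn, 6 to 13 rose and 0 to 1 fell. Fry did not call this list (adjusted p 0.101). VEGFA rose from 83.8 ± 50.8 to 291.6 ± 39.0 CPM (SD, n = 3) and DDIT4 by 1.55, and the glucose transporter SLC2A3 fell (−0.83). Of 18 NRF2 targets, 7 rose and 1 fell, and 7 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.00250; adjusted p = 0.180 with an estimated correlation). Leaving out single libraries gave 6 to 7 that rose and 1 to 2 that fell. SLC7A11, the cystine transporter that is also in the ATF4 list, rose by 2.02 and ME1 by 0.75, and TALDO1 fell (−0.29). Of 18 immediate early genes, 11 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 6.61e-09; adjusted p = 0.180 with an estimated correlation, and 10 to 11 rose and 0 fell over the libraries left out), ATF3 by 2.19 and IER3 by 2.11. Of 11 NF-kB and cytokine genes, 7 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.00543; adjusted p = 0.217 with an estimated correlation). Over the libraries left out, 3 to 6 of 12 to 14 tested rose and 1 fell. CXCL8 (2.55) and RELB (1.72) rose and NFKB1 (−0.32) fell, and the list's call was lost without DMSO replicate 1, BafA1 replicate 1 or BafA1 replicate 2 (adjusted p 0.0585 to 0.0869) and with the CPM filter (0.152). Of 8 metallothionein and zinc genes, 3 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.253; adjusted p = 0.481 with an estimated correlation, and 1 to 3 rose and 1 fell over the libraries left out), with MT1G at 2.27, MT2A at 1.17 and SLC39A10 at −0.43.

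All 28 tested mitosis genes fell with a median of −0.64, also when adjusted over the list alone (camera adjusted p = 8.00e-43; adjusted p = 0.165 with an estimated correlation, and 0 rose and 27 to 28 fell over the libraries left out), with CENPE at −1.11 and DLGAP5 at −1.05. Of 26 genes of G1/S and DNA replication, 16 fell and 1 rose, and 16 fell and 2 rose when adjusted over the list alone (camera adjusted p = 2.92e-05; adjusted p = 0.364 with an estimated correlation). Counts without 1 library were 1 to 2 that rose and 12 to 16 that fell. UHRF1 (−0.93) and RRM2 (−0.52) fell and the replication licensing factor CDT1 rose by 0.59. Of 15 heat shock genes, 13 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 8.20e-09; adjusted p = 0.180 with an estimated correlation, and 0 rose and 12 to 13 fell over the libraries left out), with CRYAB at −1.13 and DNAJA1 at −0.64. Of 36 nuclear-encoded respiratory chain genes, 18 fell and 0 rose, and 19 fell when adjusted over the list alone (camera adjusted p = 1.53e-05; adjusted p = 0.471 with an estimated correlation, and 0 to 1 rose and 12 to 19 fell over the libraries left out), with NDUFB8 at −0.62 and ATP5MC1 at −0.58. Ribosome biogenesis genes fell in 8 of 26 cases and rose in 1, also when adjusted over the list alone (camera adjusted p = 0.0142; adjusted p = 0.496 with an estimated correlation, and 1 rose and 6 to 9 fell over the libraries left out), and that call was lost without DMSO replicate 1 (adjusted p 0.0690). ODC1 (−0.48) and POLR1A (−0.43) fell and RRP12 rose by 0.36. Of 38 cytosolic ribosomal proteins, 3 rose, 1 fell and 34 did not pass, or 2 and 1 past when adjusted over the list alone (camera adjusted p = 0.272; adjusted p = 0.845 with an estimated correlation, and 1 to 15 rose and 1 fell over the libraries left out), with RPL37 at 0.40, RPL4 at 0.29 and RPL35 at −0.40. Without DMSO replicate 1 that list was called up (adjusted p 0.00503) with 15 genes that rose, and it was also called with no filter (0.00825). Of 13 histone genes, 10 fell and 1, H1-0, rose by 0.47, or 11 and 1 when adjusted over the list alone (camera adjusted p = 1.37e-05; adjusted p = 0.180 with an estimated correlation). When 1 library was left out, 1 rose and 7 to 10 fell. H1-5 (−5.41) and H1-4 (−3.46) had DMSO levels of 0.838 ± 0.952 and 2.27 ± 2.77 CPM (SD, n = 3) and were highest in DMSO replicate 2. With BafA1 they were at 0.0174 ± 0.0301 and 0.203 ± 0.0657 CPM (SD, n = 3), under the floor of 0.213 CPM, so the sizes of these changes are uncertain. Without DMSO replicate 2 their changes were −3.89 and −1.72, and H1-5 did not pass (adjusted p 0.0555), nor H1-4 when any single BafA1 library was left out (0.0566 to 0.0737), and 8 of the 13 genes fell without DMSO replicate 2.

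The neuroendocrine identity list held 6 genes that rose, 10 that fell and 22 that did not pass, or 6 and 13 past when adjusted over the list alone (camera adjusted p = 0.1004; adjusted p = 0.519 with an estimated correlation). With each library left out in turn, 3 to 8 rose and 8 to 12 fell. CALCA (0.66) and RUNDC3A (0.43) rose and TAGLN3 and GRP (both −0.62) fell. Without DMSO replicate 2 the list was called down (adjusted p 0.00876), with 4 genes that rose and 12 that fell. INSM1 stood at 444.7 ± 43.1 and 452.7 ± 12.01 CPM and CHGA at 304.1 ± 27.7 and 327.4 ± 1.505 CPM (SD, n = 3), and neither passed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.842 and 0.309), while MYCL had a log2 change of 0.19 and MYC of 0.48 (adjusted p = 0.157 and 0.348). MYCL passed without DMSO replicate 1 (adjusted p 0.00990). Of 8 regulators of other subtypes, 3 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.0299; adjusted p = 0.263 with an estimated correlation). Leaving out single libraries gave 0 that rose and 3 to 4 that fell. NEUROD1 fell from 4.105 ± 0.537 to 1.55 ± 0.319 CPM (SD, n = 3) and NEUROD4 fell too (−1.76), and the list's call was lost without DMSO replicate 1, DMSO replicate 3 or BafA1 replicate 2 (adjusted p 0.0638 to 0.0790), with no filter (0.0588), with the CPM filter (0.701) and with the DESeq2 Wald test (0.0575). YAP1 reached at most 8 counts and POU2F3 at most 4 in a library, too few to test. Of 25 genes of the non-neuroendocrine program, 3 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.503; adjusted p = 0.617 with an estimated correlation). Over the libraries left out, 2 to 3 rose and 1 to 2 fell. TGFBI (2.37) rose and TGFBR2 (−2.97) fell, and REST, a repressor of neuronal genes, rose from 0.360 ± 0.237 to 1.34 ± 0.481 CPM (SD, n = 3). Of 19 Notch pathway genes, 2 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.503; adjusted p = 0.532 with an estimated correlation, and 0 to 2 rose and 2 to 4 fell over the libraries left out), with HES4 at 1.38, DLL1 at 0.20, MAML2 at −0.86 and DLL3 at −0.43. Of these genes 0 rose and 4 fell without DMSO replicate 2.

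For antigen presentation, 6 of 17 MHC class I genes rose and 1 fell, and 8 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0874; adjusted p = 0.321 with an estimated correlation). Counts without 1 library were 5 to 7 that rose and 1 to 3 that fell. When DMSO replicate 2 was left out, 7 rose and 3 fell. That list passed without BafA1 replicate 1 or 2 (adjusted p 0.0448 to 0.0484) and with no filter (0.0160). HLA-B (1.12) and the peptide transporter TAP1 (0.95) rose. HLA-A and B2M had log2 changes of −0.12 and −0.07 and did not pass (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.322 and 0.413), although HLA-A passed without DMSO replicate 2 (adjusted p 0.0361). Of 23 interferon response genes, 2 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.503; adjusted p = 0.535 with an estimated correlation, and 1 to 4 rose and 2 to 3 fell over the libraries left out), with IRF1 at 1.39, STAT2 at 0.29, IFIT1 at −1.38 and OAS1 at −1.20. Leaving out DMSO replicate 2 gave 4 of 24 that rose and 3 that fell. Markers of other cell types were tested too. Of 8 fibroblast markers, 2 fell and 0 rose, also when adjusted over the list alone, COL1A2 (−1.43) and THY1 (−0.68) (camera adjusted p = 0.0988; adjusted p = 0.270 with an estimated correlation, and 0 to 1 rose and 2 to 3 fell over the libraries left out), and that list passed without BafA1 replicate 1 (adjusted p 0.0484) and with counts divided by 4 (0.0208). Of 5 leukocyte markers, LAPTM5 rose by 0.92 and CORO1A fell (−0.79), 1 and 1 also when adjusted over the list alone (camera adjusted p = 0.426; adjusted p = 0.509 with an estimated correlation). When 1 library was left out, 1 fell and 2 rose without DMSO replicate 2 but 0 rose without any of the others. Of 8 endothelial markers, 3 fell and 0 rose, also when adjusted over the list alone, VWF (−1.26) and CLDN5 (−1.15) most (camera adjusted p = 0.0301; adjusted p = 0.191 with an estimated correlation, and 0 rose and 2 to 3 fell over the libraries left out), and the call was lost without DMSO replicate 2 or BafA1 replicate 2 (adjusted p 0.0597 to 0.0876) and with the DESeq2 Wald test (0.0677).

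**Figure D3:**
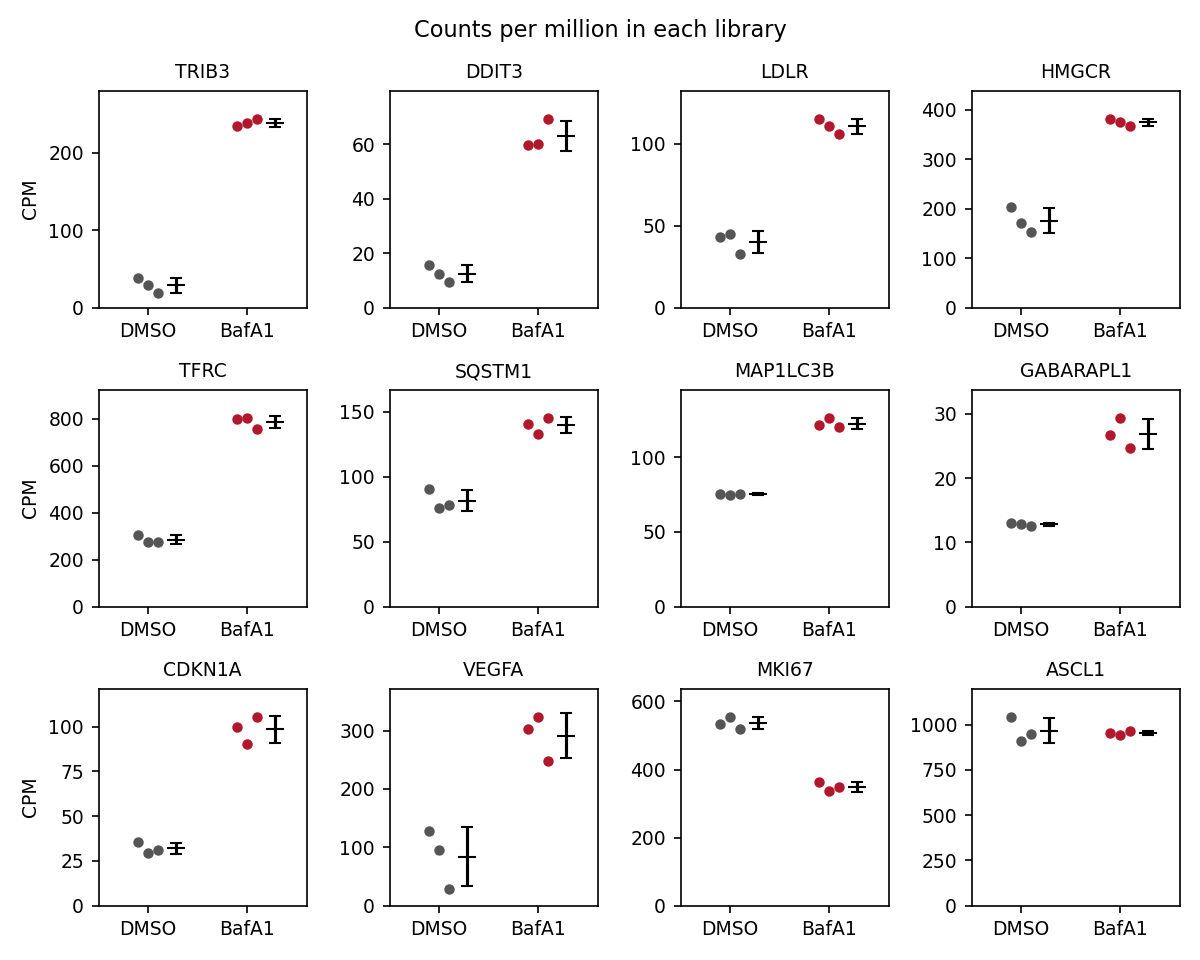
CPM of 12 genes in each of the 3 DMSO (grey) and 3 BafA1 (red) libraries, 1 point per library, with the mean and SD in black beside them. TRIB3 lies at 29.1 and 238.8 CPM on average, and ASCL1 at 965.5 and 954.0.

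Mitochondrially encoded genes took 7.24% ± 0.216 of counts with DMSO and 9.19% ± 0.252 with BafA1 (SD, n = 3). The large ribosomal RNA MT-RNR2 (chromosome MT, 1671 to 3229, plus strand, hg38) rose from 5367 ± 1256 to 13394 ± 202.2 CPM (SD, n = 3). Of 13 mitochondrial mRNAs, 5 rose and 0 fell, and of 22 tRNA genes, whose counts may hold reads of flanking transcripts, 1 rose and 8 fell. DMSO replicate 2 stood apart: 32650 genes had a count there, against 28549 to 29329 in the other libraries, and MT-RNR1 was at 4253 CPM there, against 482.9 and 509.0 in the other DMSO libraries and 1219 to 1248 with BafA1. Over all 6 libraries MT-RNR1 had a log2 change of −0.50 and did not pass (adjusted p = 0.657). The first principal component (38.9% of variance) separated the groups and the second (17.9%) set that library apart. Without it, 5784 genes changed, 5001 of them shared with the full comparison.

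Some of the largest values belonged to entries that span neighbouring genes. INO80B-WBP1 (chromosome 2, 74455088 to 74460884, plus strand, hg38) had 0 counts in all DMSO libraries and 13.8 ± 3.80 CPM with BafA1 (SD, n = 3), at least 64.8-fold higher over the floor. The sum of this entry, INO80B and WBP1 was 64.8 ± 3.08 and 63.8 ± 3.15 CPM (SD, n = 3), a log2 ratio of −0.02. SENP3-EIF4A1 had a log2 change of −3.38 and the sum with SENP3 and EIF4A1 one of −0.52; for ARHGAP11A-SCG5 these were −2.28 and −0.30.

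Of the 33 lists, camera called 15 up and 8 down at the preset correlation and 0 with an estimated correlation (5 at an unadjusted p under 0.05), fry called 26 as moving in 1 direction (22 of the 23 and, with adjusted p 0.00683 to 0.0262, the MHC class I, interferon, fibroblast and metallothionein lists), and other splits of these 6 libraries gave up to 16 camera calls. Those splits mix DMSO and BafA1 libraries, so their calls are not a count expected without treatment. Even the ATF4 list, where 31 of 31 genes rose, had an unadjusted camera p of 0.00936 with an estimated correlation. With 3 libraries per group, the lack of a call in that test therefore does not show that a list was unchanged. Median, mean and test differed in sign for the V-ATPase, Notch and leukocyte lists. The fold change of some named genes past the threshold moved by more than 1.5-fold without 1 library or another. Besides ZBTB20, H1-5 and H1-4, these were, on the log2 scale, REST (1.89, and 2.58 without DMSO replicate 1), IER3 (2.11, and 2.95 without DMSO replicate 3), MEF2B (3.12, and 3.72 without DMSO replicate 2), SENP3-EIF4A1 (−3.38, and −2.62 without DMSO replicate 2 or −4.63 without BafA1 replicate 1) and ARHGAP11A-SCG5 (−2.28, and −3.24 without BafA1 replicate 2). Mean levels were under the floor of 0.213 CPM with DMSO for PCSK9, TGFBI, CXCL8, IER3 and MT1G and with BafA1 for TGFBR2, so their folds are uncertain too. Of the 121 named genes past the threshold, 22 did not pass without 1 library or another. Besides those given with their values above, these were PMVK, POLH, SLC2A3, STAT2, HES4, IER3, LAPTM5 and DLL1, each without 4 or 5 of the 6 libraries in turn (highest adjusted p 0.1 for PMVK, 0.110 for POLH, 0.121 for SLC2A3, 0.112 for STAT2, 0.143 for HES4, 0.154 for IER3, 0.152 for LAPTM5 and 0.146 for DLL1), and REST (0.0931), TFEB (0.101), CRYAB (0.0563), FUNDC1 (0.0661), IFIT1 (0.0642), MT1G (0.0819), MT2A (0.0581), NFKB1 (0.0817), RPL4 (0.0582), BCL2L1 (0.0646) and ARHGAP11A-SCG5 (0.0572), each without 1 to 3 of them.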

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

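All alternatives were planned before the data were examined except counts divided by 4 and the removal of 3 misplaced list members. Leaving out each library in turn gave 3756 to 5784 changed genes and 1659 to 2829 lower genes, the smallest counts without BafA1 replicate 1 (3756) and BafA1 replicate 3 (3827, with 1734 lower). Requiring a CPM of at least 5 in 3 libraries left 279 genes at least 2-fold higher and 151 at least 2-fold lower, since fewer genes were tested. Testing against a fold of 1.5 with glmTreat left 588 changed genes, 404 higher and 184 lower, of which 321 and 160 differed at least 2-fold, by construction of a stricter test. The share of higher among changed genes was 53.4%, 61.0% without a filter, 68.7% with glmTreat and 47.4% with library size only. The DESeq2 Wald test called 6064 genes. With an estimated correlation 0 lists were called, in place of 23. No pairing by replicate number was seen (correlations of same-numbered deviations −0.0059, −0.018 and −0.020), which does not show that the samples were unpaired. With a replicate block 4668 genes and 23 lists were called, with 4575 of those genes shared with the unblocked comparison. ASCL1 changed sign without DMSO replicate 1 (0.044; −0.059 to 0.044 over the libraries left out) and without a filter (0.014), and INSM1 without DMSO replicate 2 (−0.053; −0.053 to 0.074) and with library size only (−0.0035). The V-ATPase list changed its direction without DMSO replicate 2 (adjusted p 0.467; 0.467 to 0.825 over the libraries left out), with the CPM filter (0.852), library size only (0.943), official-looking symbols (0.994) and counts divided by 4 (0.994), and the metallothionein list with the CPM filter (0.955). None of these passed the threshold, and the cause was not tested. Over the alternatives, 1735 of 1891 values of named genes kept direction and side of the threshold, 149 lost the call, 3 gained it and 4 changed sign, and of 558 list results 502 were kept, 38 lost, 12 gained and 6 changed direction. Of named genes, 67 lost their call with glmTreat against a fold of 1.5, 7 with a replicate block, 7 with no filter, 3 with library size only and 2 with the DESeq2 Wald test. In the simulation, 2-fold changes were recovered in 46.3% of all genes and 76.9% of those at or above 1 CPM, at 1 depth only.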

Other observations

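The pathway tests, the set of small nuclear-encoded RNAs, both tests on mitochondrial rRNA, the test on the HIF list and the reading of the histone baseline were chosen after the results had been seen, and the gene set of the histone test was corrected then. Of 319 pathways in the deposited annotation, camera called 49 at the preset correlation. Among those not called were HIF-1 signaling (22 rose and 14 fell of 92) and apoptosis (35 rose and 19 fell of 122), with camera adjusted p of 0.144 and 0.273. The fixed lists of HIF targets and apoptosis regulators were called. Of 43 tested proteasome genes, 29 fell, 0 rose and 14 did not pass (30 fell and 1 rose without DMSO replicate 2), with PSMB5 at 106.8 ± 8.70 and 74.3 ± 5.55 CPM (SD, n = 3) and PSMD1 at −0.52 on the log2 scale (camera adjusted p = 6.72e-07 over 319 pathways; adjusted p = 0.820 with an estimated correlation). Of 132 spliceosome genes, 55 fell, 5 rose and 72 did not pass, HNRNPM from 394.9 ± 21.7 to 253.5 ± 2.51 CPM (SD, n = 3) (camera adjusted p = 6.72e-07; adjusted p = 0.869 with an estimated correlation). Without DMSO replicate 2, 71 of the spliceosome genes fell and 4 rose. Of 119 lysosome genes, 34 rose, 9 fell and 76 did not pass (camera adjusted p = 0.00282; adjusted p = 0.820 with an estimated correlation), and of 133 autophagy genes 45 rose, 11 fell and 77 did not pass (camera adjusted p = 7.53e-04; adjusted p = 0.820 with an estimated correlation). Of 32 SNARE genes of vesicle fusion, 13 rose and 0 fell, STX3 by 1.02 (camera adjusted p = 0.0187; adjusted p = 0.820 with an estimated correlation). Of 44 genes of aminoacyl-tRNA synthesis, 13 rose and 7 fell, with WARS1 at 1.39 and GARS1 at 1.36 (camera adjusted p = 7.18e-05; adjusted p = 0.820 with an estimated correlation). These examples are among the members with the largest changes, chosen after their values were seen, and are not always the largest. LSM3 (−0.80) and SNRPG (−0.77) fell more than HNRNPM (−0.64), and CARS1 (1.37) rose slightly more than GARS1.

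Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 5750 genes and the highest other split 1, and 1 of the 10 splits gave as many genes as the real one, itself. For lists the real split gave 23 calls and the highest other 16, and again 1 of the 10 splits gave as many lists. Each other split holds DMSO and BafA1 libraries on both sides, so the difference between treatments adds to its spread within groups. Its counts are therefore not those that chance alone would give.

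DMSO replicate 2 held 14 small nuclear-encoded RNAs without a poly(A) tail, RN7SL2 and RN7SK among them, at 799.8 CPM in sum against 4.47 to 7.82 in the other 5 libraries, 102-fold over the highest (95% counting interval 85.3 to 125). Genomic DNA is argued against as the source of these RNAs, since it would add reads to every gene. In that library 95 olfactory receptor genes summed to 1.08 times the highest other library (0.984 to 1.18), or 72.4 CPM against 207.4 for RN7SK alone. They summed to 59.8 and 49.1 CPM in DMSO replicates 1 and 3. The lncRNA share of counts was 3.11% in DMSO replicate 2 against 1.66% to 1.81% in the other libraries, and its cause was not tested. Incomplete poly(A) selection was tested before its value was seen with replication-dependent histone and snoRNA genes, whose sum was 1.10 times the highest other library (1.06 to 1.13; 1.02 in a first form of the set that wrongly held H1-10), under the bound of 1.5 set against it. That bound was unsound, since H2BC21, H2BC12 and H1-2 alone held 38.9% of the sum in the other libraries, a captured baseline of up to 463.2 CPM. Over it a ratio of 1.5 needs 231.6 CPM, or 29.2% of the rise of the small RNAs, so that a smaller share would stay hidden. Incomplete selection therefore stays open, and no biological explanation was tested. Outside these sets, MALAT1 and MT-RNR1 were also highest in DMSO replicate 2, 4.76-fold and 3.41-fold over the highest other library. MT-RNR2 was not, at 0.504 times BafA1 replicate 2.

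MT-RNR2 was 2.88-fold and MT-RNR1 2.49-fold higher with BafA1 than in DMSO replicates 1 and 3, log2 ratios of 1.53 and 1.31. In the full comparison MT-RNR1 did not pass and had the other sign (−0.50, adjusted p = 0.657), because of DMSO replicate 2. More mitochondrial RNA of every kind is argued against, since the 13 mitochondrial mRNAs had a median log2 ratio of 0.17 (quartiles 0.012 to 0.25). For weaker poly(A) selection with BafA1, the sum of the small nuclear-encoded RNAs had a log2 ratio of 0.45, with 0.0045 to 0.81 between extreme libraries, while replication-dependent histone and snoRNA genes went the other way with −0.51 (−0.75 to −0.27). Histone genes also fell as a list, so their fall does not separate the explanations. MALAT1 has no poly(A) tail of the usual kind and was 4.76-fold over the highest other library in DMSO replicate 2. Its log2 ratio with BafA1 was −0.06 (−0.25 to 0.18). MALAT1 is 1 gene with a baseline of 462.4 CPM in DMSO replicates 1 and 3. The small RNAs rose only from 4.61 CPM there to 6.29 CPM with BafA1, and a rise of a few CPM would stay hidden over that baseline. MALAT1 therefore cannot decide on weaker selection. Between extreme libraries the sum of the small RNAs reached at most 0.81, under the lowest ratios of MT-RNR2 (1.46) and MT-RNR1 (1.26). If weaker selection raises RNAs without a tail alike, this would argue against it as the only cause. Such RNAs did not differ alike in DMSO replicate 2, where the small RNAs were 102-fold over the highest other library. There MT-RNR1 was at 4253 CPM, against 482.9 and 509.0 in DMSO replicates 1 and 3, and MT-RNR2 at 6807, against 4505 and 4788. The premise is therefore unproven. At 0.81 the sum of the small RNAs also exceeded the bound set for this test, so the test could not tell. Weaker selection stays open. An effect of BafA1 on mitochondrial rRNA or its tails is an untested hypothesis.

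In the HIF list, 8 of the 9 genes that rose were outside glycolysis. HIF activation as the common cause for the whole list was tested on all members, and the 12 glycolytic members had a mean log2 change of 0.14 (SE 0.30 between libraries) against 0.67 (SE 0.27) for the 20 others. The first minus 0.5 times the second, −0.19 (SE 0.17), lay within 2 SE of 0, so this explanation stays open. A difference between the cultures was not tested, and the glycolytic mean ran from −0.60 to 0.33 among the DMSO libraries around the mean of all 6. DDIT4 and TFRC are also in the ATF4 and iron lists, and without genes of other lists 27 members remained with a camera adjusted p of 0.00570 (adjusted p = 0.782 with an estimated correlation).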
